A study of Euphorbia esula with 12 samples.

How the data were processed

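Polyadenylated RNA from crown buds of leafy spurge was sequenced in pairs of reads from strand-specific libraries, 12 in all, 4 per dormancy state. The authors' deposited table gives expected counts, estimated per contig and per component (an assembled gene) of a transcriptome, which per the submitters' processing notes come from RSEM. Versions of RSEM and of the assembly, and the aligner, are not given in the sources used here, and no genome was used, so components have no genomic position. The table holds 569227 contigs in 223732 components, of which 100901 have a count in any library, and gives for 62913 components a best Arabidopsis hit. The contigs of 8576 components hit more than 1 Arabidopsis locus. Each component's value is the sum of its contigs to within 0.04. The table also holds the authors' posterior probability of a difference for each pair of states, from a tool that is not given in the sources used here.

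Libraries were grouped by dormancy state. The question asked of each pair of states was which components differed. Expected counts per component were rounded to whole numbers, scaled by the TMM method (factors from 0.964 to 1.029), filtered with filterByExpr defaults and tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood F test, with group as the only term, on all 12 libraries together. Of all components, 18885 were tested, 16249 of them with an Arabidopsis hit, at a common biological coefficient of variation of 0.133. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. They measure the spread between these samples, which for endodormant buds includes 2 libraries that are nearly copies. Folds and log2 changes come from the fit with each library weighing alike, while endodormant means count replicates 3 and 4 as 1 sample. Errors of log2 changes are standard errors from the fit, and levels are counts per scaled library total in the unit CPM, with a prior count of 2 where on the log2 scale. Changing the scaling moved the median log2 change of all tested components by at most 0.02. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

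Gene lists, 29 in all, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, where at least 5 members were tested. Of these lists 22 were given as Arabidopsis loci and 7 as words in the annotation. Across them 13 entries were dropped because the description named another gene. The tests, lists, comparisons and rule for named genes were chosen before the data were examined. The rule names components with an annotation, a mean of at least 5 CPM and groups that do not overlap: the 5 largest rises and 5 largest falls past the threshold in endodormant against paradormant and in ecodormant against endodormant buds, and 3 of each in ecodormant against paradormant buds, 1 per locus. It adds for the first pair of comparisons, from each list, up to 3 members with the smallest adjusted p if camera passed and up to 2 otherwise, at a mean of at least 1 CPM. In each comparison it adds up to 2 components, those of highest mean CPM, matching each of EPSPS, SVP or AGL24, FT or TSF, BRC1 and DRM1 or DRM2, whatever their values. Of these, FT (8 components), TSF (12) and DRM2 (1) had too few counts to be tested, and AGL24 and BRC1 matched 0 components.

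Depth sets a floor of 3 counts over a group. Folds against a group with 0 counts are given as lower bounds at that floor, and folds against 1 to 3 counts as a ratio with its 95% counting interval. Intervals and floors cover counting error only. Per-library differences were also checked by chi-square between libraries of a group, over components with a summed count of at least 40.

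The procedure was tested on simulated data with 12 libraries of the real sizes, 18357 components tested and 200 changed. Components and libraries were drawn independently, with no near-copies, no split of the endodormant group and no correlation between genes. The simulation therefore cannot test the preset correlation used in camera. In endodormant against paradormant buds it recovered 28.8% of components changed 1.5-fold, 59.7% at 2-fold and 92.3% at 4-fold, with 7 unchanged components called. In ecodormant against endodormant buds it recovered 22.7%, 61.2% and 92.3%, with 5 unchanged components called. Ecodormant against paradormant buds, with no change put in, gave 1 call. Of 28 lists, camera called the 1 raised on purpose (adjusted p = 4.86e-26) and 1 unchanged list.

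Alternatives tried were DESeq2 1.42.0 size factors and the DESeq2 test, limma-voom, no filter and a filter of 5 CPM in 4 libraries, a 2-fold limit, contigs in place of components, a fit of only the 2 groups compared, a block for replicate number, each library left out in turn, an estimated correlation, 1 component per locus and principal components of the 1000 components with the largest variance. Added after the data were seen were endodormant replicates 3 and 4 summed to 1 sample, and endodormant replicates 1 and 2 or 3 and 4 left out. Alternatives for FPKM or TPM did not apply, as the table gives expected counts. The authors' probabilities were compared with the calls here and not otherwise used.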

Results

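Leafy spurge (Euphorbia esula) is a perennial weed that regrows from buds on its crown, below the soil line. Polyadenylated RNA of these crown buds was sequenced in 12 libraries, 4 biological replicates from each of 3 states of dormancy, all from plants sprayed with glyphosate at 2.24 kg ai/ha. Paradormant buds, held back by the rest of the plant, were taken 7 days after the spray from plants in a greenhouse. Endodormant buds, held back by signals within the bud, were taken after 12 weeks in which temperature went from 27 C down to 10 C and day length from 16 h down to 8 h. Ecodormant buds, held back by the environment alone, had 8 more weeks at 7 C under 8 h of light. The series has 0 libraries from unsprayed plants, so each comparison is between dormancy states among sprayed plants, and time since the spray differs with the state. Library totals ran from 3356634 to 4057495 expected counts, with 3915420, 3814123, 3673195 and 4057495 in paradormant replicates 1 to 4, 3541887, 3582278, 3613270 and 3356634 in endodormant replicates 1 to 4, and 3524793, 3458946, 3663326 and 3619001 in ecodormant replicates 1 to 4.

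The main axis of the data set the dormancy states apart. Temperature, bud age and time since the spray follow the same order, so this axis cannot be assigned to dormancy alone. The first principal component held 59.0% of the variance and set paradormant libraries (scores from -84.0 to -78.7) against ecodormant libraries (59.3 to 68.8), with endodormant libraries between them (8.5 to 30.4). The second component set the endodormant libraries apart from both other groups. It also parted the endodormant libraries into 2 pairs, with scores of -29.5 and -28.7 for replicates 1 and 2 and -63.4 and -64.0 for replicates 3 and 4. Endodormant replicates 3 and 4 differed by little more than sampling noise: the chi-square per component was 1.22 between them over all components (p = 3.88e-72) and 1.13 over the 355 components made of a single contig with whole counts (p = 0.0479), while the 17 other pairs of libraries within a group gave 2.28 to 10.54 and 1.93 to 6.3. These replicates were therefore counted as 1 sample in each mean ± SD of the endodormant group (n = 3). Folds and log2 changes come from the fit, in which all 4 endodormant libraries weigh alike, so they can differ from the ratio of the means beside them.

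**Figure D1:**
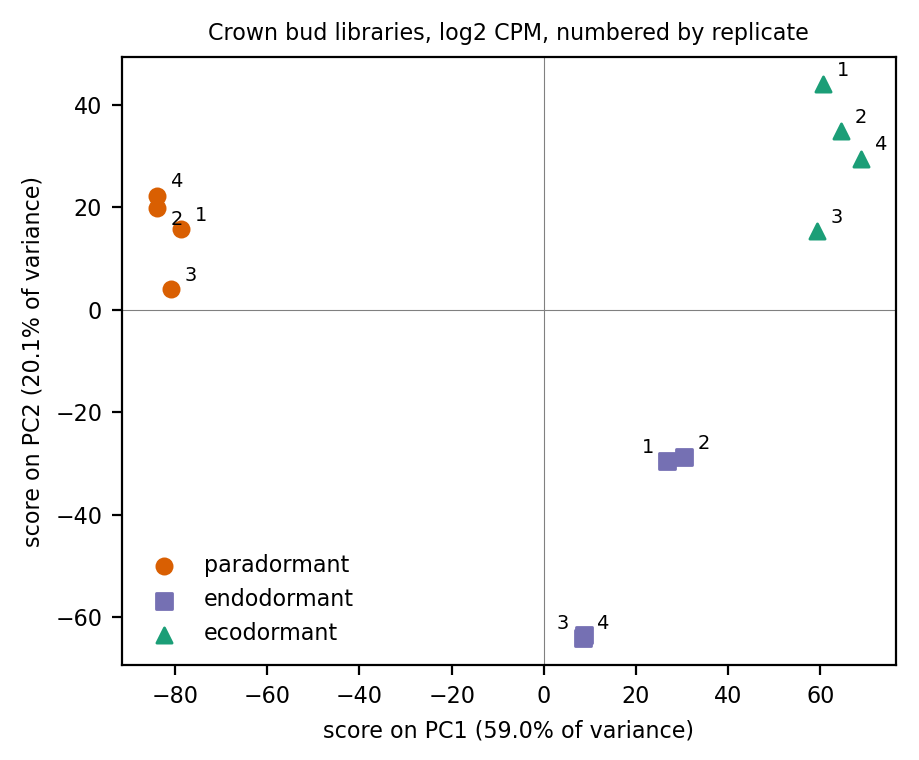
Scores of the 12 crown bud libraries on the first (59.0% of variance) and second principal component of log2 CPM, numbered by replicate; circles, squares and triangles are paradormant, endodormant and ecodormant libraries. The groups lie apart, and endodormant replicates 1 and 2 lie 33.9 units above replicates 3 and 4 on the second component.

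Endodormant against paradormant buds shows what differed after the ramp down of temperature and day length. Some transcripts of proteins that protect cells from drying and freezing were far higher in endodormant buds, although the cold acclimation list as a whole did not pass. A component matching the dehydrin gene ERD10 (comp116004_c0) rose 14.9-fold, from 101.4 ± 17.2 CPM (SD, n = 4) to 1606.0 ± 331.4 CPM (n = 3). A late embryogenesis abundant (LEA) protein (comp102477_c0) rose 124.7-fold, from 1.08 ± 0.693 to 161.0 ± 71.3 CPM. The gene annotated as DORMANCY ASSOCIATED MADS-BOX 2 (comp101885_c0, best Arabidopsis hit SVP, AT2G22540), a transcription factor of a class tied to bud dormancy, rose 17.4-fold, from 1.42 ± 0.294 to 28.1 ± 10.3 CPM (33.8 and 34.3 CPM in endodormant replicates 1 and 2, 16.5 and 16.1 CPM in 3 and 4). ACO1 (comp118906_c0), an ACC oxidase that makes ethylene, was 50.9-fold lower, falling from 86.0 ± 7.30 to 1.45 ± 0.789 CPM. A glutathione S-transferase of a family that detoxifies herbicides and other compounds (comp105439_c0, AT2G29420) was 94.3-fold lower, at 145.7 ± 35.3 CPM in paradormant and 1.39 ± 0.438 CPM in endodormant buds. EPSPS (comp123652_c0), the enzyme that glyphosate inhibits, did not pass the test, at 104.7 ± 6.31 and 97.3 ± 9.15 CPM (log2 change -0.07 ± 0.08 SE, adjusted p = 0.496).

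Of 18885 components tested with edgeR, 4308 rose and 4137 fell, and 1745 of the rises and 1336 of the falls were at least 2-fold. With endodormant replicates 3 and 4 counted as 1 sample, every sample of one group lay above every sample of the other in 46.5% of the components, where chance gives 5.7%. With endodormant replicates 3 and 4 summed to 1 sample, 8228 components changed, among them 93.5% of the 8445. Of the tested components, 4968 have, in the authors' deposited table, a posterior probability of difference of at least 0.95, and 4931 of these are among the 8445. Of the 27 gene lists tested with camera, 5 moved up and 4 down against the other genes, and the calls of 4 (ethylene, starch and sucrose, glutathione S-transferases, LEA proteins) held with an estimated correlation.

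Starch and sucrose genes rose, and so did some LEA proteins. Of 38 tested members of the starch and sucrose list, 25 rose and 3 fell, the same numbers when adjusted over the list alone (median log2 change 0.89, camera adjusted p = 3.40e-09, adjusted p = 0.0341 with an estimated correlation). The list moved with the split of the endodormant libraries, with a mean centred log2 CPM of 0.29 and 0.36 in replicates 1 and 2 and 0.59 and 0.63 in replicates 3 and 4. Among its members, the starch-degrading beta-amylase BAM1 (comp116683_c1) rose 6.33-fold, from 21.8 ± 1.62 to 145.9 ± 26.5 CPM, the alpha-glucan phosphorylase PHS2 (comp131937_c0) rose 6.95-fold, and the starch phosphatase SEX4 (comp102735_c0) rose 4.74-fold. Of 8 LEA proteins and dehydrins, 4 rose and 0 fell, also when adjusted over the list alone (median 0.69, adjusted p = 5.53e-04, adjusted p = 0.0341 with an estimated correlation). Their mean centred log2 CPM was 0.71 and 0.72 in endodormant replicates 1 and 2 and 0.48 and 0.44 in replicates 3 and 4. Of these comp112460_c0 (AT3G53040) rose 33.5-fold to 777.4 ± 274.8 CPM (877.4, 988.1, 464.6 and 468.6 CPM in replicates 1 to 4), and a Lea5 protein (comp105245_c0) rose 1.94-fold. A group 3 LEA protein (comp75470_c0, AT2G36640) had 3 counts in all paradormant libraries together and 57.9 ± 28.0 CPM in endodormant buds (76.7, 71.2, 22.3 and 29.1 CPM), a ratio of 258.6 with a counting interval of 88.1 to 1257.1. The cold acclimation list was mixed, with 11 of 24 members higher and 8 lower (11 and 10 adjusted over the list alone, adjusted p = 0.439). It passed with 1 component per Arabidopsis locus (median 1.25, adjusted p = 0.00105, against up to 0.663 in other alternatives). Its members ERD10, above, and LOS2 (comp115385_c0), which encodes the glycolytic enzyme enolase, rose, the latter from 1229.5 ± 68.7 to 3804.4 ± 366.4 CPM.

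Genes of light capture and timekeeping were higher after the ramp down. Of 30 photosynthesis components, 16 rose and 1 fell, unchanged when adjusted over the list alone (median 0.67, adjusted p = 9.12e-05), a call lost at adjusted p = 0.517 with an estimated correlation. RCA (comp104693_c1), the activase of Rubisco, rose 4.97-fold, from 22.1 ± 9.51 to 113.0 ± 12.5 CPM, the photosystem II subunit PSBR (comp126970_c0) rose 5.72-fold and the Rubisco small subunit RBCS1A (comp102721_c0) 2.57-fold. Of 24 circadian clock and light signalling components, 15 rose and 1 fell (15 and 2 adjusted over the list alone, median 0.66, adjusted p = 1.47e-04), with adjusted p = 0.0838 with an estimated correlation. Its mean centred log2 CPM was 0.20 and 0.28 in endodormant replicates 1 and 2, 0.00 and -0.02 in replicates 3 and 4, and from -0.80 to -0.60 in paradormant libraries. RVE8 (comp115633_c0), a morning-phased clock activator, rose 3.59-fold, from 25.1 ± 3.05 to 95.8 ± 21.5 CPM, the blue-light receptor FKF1 (comp119728_c0) rose 6.68-fold and the pseudo-response regulator PRR5 (comp118278_c2) 5.90-fold.

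Hormone lists moved in different ways. Of 17 ethylene components, 14 fell and 1 rose, also when adjusted over the list alone (median -0.64, adjusted p = 8.56e-12, adjusted p = 0.0341 with an estimated correlation). Besides ACO1, the ethylene receptor ETR2 (comp133343_c0) fell from 363.2 ± 29.4 to 92.6 ± 13.7 CPM. The F-box gene EBF1 (comp136486_c0), which targets a transcription factor of ethylene signalling for breakdown, fell by 0.96 ± 0.07 on the log2 scale. Of 29 gibberellin components, 15 fell and 3 rose, also when adjusted over the list alone (median -0.78, adjusted p = 0.0165, adjusted p = 0.0601 with an estimated correlation and 0.0892 with 1 component per locus). The ent-kaurene oxidase gene GA3 (comp121172_c0) was 6.23-fold lower and the gibberellin-regulated GASA14 (comp116270_c0) 10.1-fold lower, while the gibberellin-producing GA20OX1 (comp113515_c0) rose 7.42-fold, from 4.18 ± 0.919 to 31.7 ± 1.68 CPM. The abscisic acid list did not pass (16 of 48 rose and 17 fell, 17 and 17 adjusted over the list alone, adjusted p = 0.55). Within it ABA2 (comp94718_c0), an enzyme late in abscisic acid synthesis, was 7.76-fold lower, and PP2CA (comp122597_c1), a phosphatase that dampens abscisic acid signalling, rose 13.4-fold. Auxin (4 of 27 rose, 6 fell, adjusted p = 0.537), cytokinin (4 of 21 rose, 10 fell, 0.0751), strigolactone and branching (3 of 10 rose, 1 fell, 0.333), jasmonate (5 of 19 rose, 2 fell, 0.55) and salicylate and defence (1 of 12 rose, 4 fell, 0.21) did not pass either. Adjusted over the list alone these counts were 4 and 5, 4 and 11, 3 and 1, 5 and 2, and 1 and 4. The salicylate list passed with 1 component per locus (adjusted p = 0.0291) and without endodormant replicates 1 and 2 (0.0276), with 0.657 the highest of its alternatives. Members that changed include the auxin-response repressor IAA9 (comp112040_c0, 2.15-fold up) and AXR1 (comp119015_c0, log2 change -0.57), the cytokinin oxidase CKX5 (comp131032_c1, -2.76) and the response regulator ARR9 (comp74955_c0, -1.85), D27 (comp115798_c0, 4.75 ± 0.66, and 3.56 without endodormant replicates 1 and 2) of strigolactone synthesis and the receptor KAI2 (comp103923_c0, 1.48), the jasmonate genes LOX3 (comp126550_c0, -0.72) and JAR1 (comp130019_c0, 0.95), and the defence genes PR1 (comp87604_c0, -5.01 ± 0.48) and WRKY40 (comp116411_c1, -2.05).

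Glutathione S-transferases and UDP-glycosyltransferases, families that detoxify foreign compounds, were lower in endodormant than in paradormant buds, which were harvested 7 days after the spray. Of 25 glutathione S-transferase components, 17 fell and 4 rose, also when adjusted over the list alone (median -1.42, adjusted p = 2.27e-08, adjusted p = 0.0341 with an estimated correlation). An abundant member (comp128119_c0, AT1G10370) fell from 1022.9 ± 127.5 to 279.6 ± 18.8 CPM, while comp119181_c0 (AT1G02930) rose from 830.4 ± 48.5 to 1428.4 ± 56.0 CPM. Of 56 UDP-glycosyltransferases, which attach sugars to hormones and foreign compounds, 24 fell and 13 rose (26 and 13 adjusted over the list alone, median -0.37, adjusted p = 9.98e-04, adjusted p = 0.144 with an estimated correlation). Members comp121473_c0 (AT4G34138), comp88488_c0 (AT4G15480) and comp104176_c0 (AT1G73880) were 22.3-fold, 8.94-fold and 5.58-fold lower. A glucuronosyltransferase-like component outside the list (comp82823_c0, AT1G22340) was 106.2-fold lower, at 57.1 ± 16.1 CPM before and 0.430 ± 0.380 CPM after. ABC transporters did not pass (24 of 103 rose and 40 fell, 26 and 41 adjusted over the list alone, adjusted p = 0.0614), with comp109384_c0 (AT3G53510) up 15.4-fold and the multidrug-resistance type comp138195_c0 (AT3G13080) 5.65-fold lower. Reads of such multigene families can be shared between paralogs, so the change of a single member is less certain than that of its family.

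Of 39 cell cycle and DNA replication components, 15 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.43, adjusted p = 0.0269, adjusted p = 0.657 with an estimated correlation). Cyclin CYCD1;1 (comp131195_c0) rose 2.04-fold, the replication helicase subunit MCM2 (comp137427_c0) 1.88-fold and the retinoblastoma homolog RBR1 (comp119067_c0) 1.58-fold. This list moved with the split of the endodormant libraries: its mean centred log2 CPM was 0.37 and 0.07 in replicates 1 and 2 and 0.69 and 0.72 in replicates 3 and 4. The call ended with replicates 3 and 4 summed (adjusted p = 0.0684), without replicate 3 (0.0747), without replicate 4 (0.0742) and without both (0.469). The phenylpropanoid and shoot meristem lists moved with the same split, at 0.18, 0.04, 0.78 and 0.71 and at -0.12, -0.29, 0.39 and 0.34 in replicates 1 to 4.

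The remaining lists did not pass. They were the shikimate pathway (2 of 25 rose, 8 fell, adjusted p = 0.142), phenylpropanoids (9 of 31 rose, 8 fell, 0.629), flowering-time regulators (6 of 24 rose, 7 fell, 0.911), senescence (3 of 9 rose, 1 fell, 0.744), oxygen and oxidative stress (5 of 18 rose, 8 fell, 0.698), phloem (4 of 7 rose, 0 fell, 0.439), shoot meristem (4 of 11 rose, 1 fell, 0.353), ribosomal proteins (29 of 176 rose, 40 fell, 0.51), heat shock proteins (11 of 74 rose, 24 fell, 0.0614) and expansins with xyloglucan endotransglucosylases (3 of 19 rose, 6 fell, 0.979). Adjusted over the list alone, phenylpropanoids had 11 and 8, phloem 5 and 1 and ribosomal proteins 26 and 38, and the others had the same numbers. The shikimate list passed without endodormant replicates 3 and 4 (0.0182, against up to 0.657 in other alternatives), and oxidative stress passed with 1 component per locus (median -0.73, 0.0196, against up to 0.983). Heat shock proteins passed without paradormant replicate 1 (0.00805), paradormant replicate 2 (0.0264) or endodormant replicate 4 (0.0481), and ABC transporters without paradormant replicate 2 (0.0347) or 3 (0.0407). Both lists also passed with a block for replicate number (0.0329 and 0.0406) and without endodormant replicates 3 and 4 (0.0402 each), with 0.587 and 0.514 the highest of their alternatives. Median, mean and camera direction differed in sign for phenylpropanoids (0.01, 0.26, down), flowering (-0.04, 0.07, up), senescence (-0.22, 0.17, up), oxidative stress (-0.04, 0.04, down) and expansins (-0.16, 0.16, down). Camera was not run on the secondary wall list (1 tested, 0 changed) or the laticifer list, in which 3 of 4 rubber particle components rose, among them SRPP-1 (comp109321_c0, 3.68-fold) and SRPP-3 (comp91223_c0, 1.94-fold).

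Single members of these lists nevertheless changed. The shikimate enzyme DHQ-SDH (comp131455_c0) was 2.64-fold lower and the aminotransferase PAT (comp112119_c0) 1.74-fold lower. The lignin enzymes 4CL1 (comp126165_c0) and OMT1 (comp111762_c1) fell by 1.19 ± 0.11 and 2.61 ± 0.23 on the log2 scale, and the vernalization gene VRN1 (comp102529_c0) fell by 1.67 ± 0.12. SVP (comp110466_c0) rose 1.76-fold. The oxygen-binding hemoglobin HB1 (comp89047_c0) was 29.9-fold lower and the glutathione reductase GR1 (comp126383_c0) rose 3.19-fold. SAG29 (comp134765_c0) rose 4.07-fold, SAG21 (comp107102_c0) was 3.73-fold lower (log2 change -2.86 without endodormant replicates 1 and 2), the sucrose carrier SUC2 (comp130060_c1) rose 1.33-fold, and the meristem genes AS1 (comp136420_c0) and UFO (comp110309_c0) rose 1.61-fold and 2.18-fold. An expansin (comp119080_c1) and a xyloglucan endotransglucosylase (comp123985_c3) rose 8.86-fold and 22.1-fold. Ribosomal proteins P2 (comp102508_c0) and L12 (comp112471_c1) were 5.06-fold and 6.12-fold lower, a chaperone-binding protein (comp135915_c0, AT1G78120) was 51.6-fold lower and an HSP70-type chaperone (comp129972_c0, AT5G02500) rose from 3944.8 ± 281.4 to 7596.8 ± 199.6 CPM. The phloem gene SEOR1 (comp114914_c1) rose 1.73-fold (adjusted p = 0.0248), but not without paradormant replicate 1 (0.0516), paradormant replicate 4 (0.0796), endodormant replicate 4 (0.0892) or endodormant replicates 3 and 4 (0.169), nor in DESeq2 (0.0804). DRM1 (comp136283_c0), a dormancy-associated gene, did not pass (0.09 ± 0.11, adjusted p = 0.551).

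Further components were among the largest rises and falls. Among rises, comp136142_c0 (a pentatricopeptide repeat protein, AT3G48810) went from 0.254 ± 0.206 to 31.2 ± 11.2 CPM, comp125021_c0 (AT4G25580) rose 94.6-fold to 721.4 ± 273.6 CPM and comp118595_c0 (AT3G03341) rose 66.7-fold. Among falls, a sulfate transporter (comp117662_c0, AT5G19600) fell by 7.39 ± 0.77 on the log2 scale, from 54.0 ± 22.4 to 0.379 ± 0.656 CPM. Its endodormant counts came from replicate 1 alone (1.14 CPM), without which the group had 0 counts and the fall was at least 187-fold against a floor of 3 counts. A component annotated as the cullin ATCUL1 (comp98726_c0, AT4G02570) had 3 counts in endodormant libraries, a ratio of 97.0 with a counting interval of 32.9 to 473.0. The component comp98228_c0 (AT3G29970) was at 22.4 ± 8.57 CPM in paradormant buds and had 0 counts in endodormant buds, at least 104-fold lower against a floor of 3 counts over the group. Several of these changes moved with the endodormant split. Without endodormant replicates 1 and 2 the log2 change was 5.96 for comp136142_c0 (6.58 with all libraries), 5.90 for comp125021_c0 (6.56), 5.21 for comp118595_c0 (6.06), 6.13 for the LEA protein comp102477_c0 (6.96), -5.74 for PR1 (-5.01) and -5.61 for HB1 (-4.90). Without replicates 3 and 4 it was -6.37 for ACO1 (-5.67) and -7.47 for comp82823_c0 (-6.73). Without paradormant replicate 1, comp136142_c0 had 2 counts in paradormant libraries, a ratio of 162.1 with a counting interval of 44.6 to 1342.9.

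**Figure D2:**
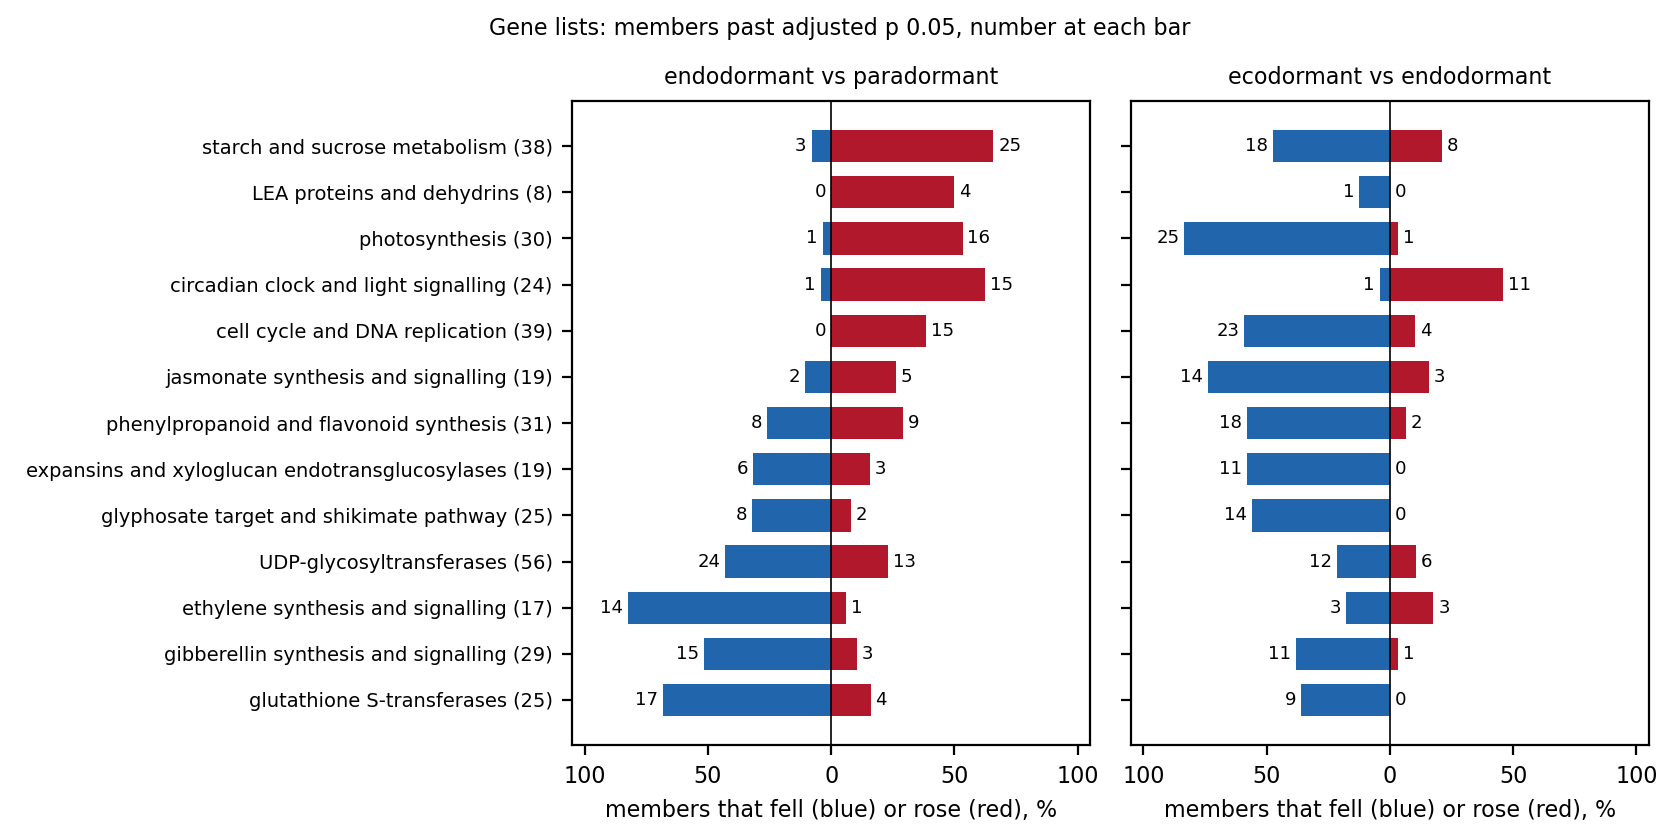
Share of tested members (number in brackets) of 13 gene lists that fell (blue, to the left) or rose (red, to the right) past adjusted p 0.05, in % of the tested members, with the number of members at each bar. Starch and sucrose genes mostly rose (25 of 38) and ethylene genes mostly fell (14 of 17) in endodormant against paradormant buds. Photosynthesis genes mostly fell (25 of 30) in ecodormant against endodormant buds.

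Ecodormant against endodormant buds shows what differed after 8 further weeks of cold at the same day length. Some genes of DNA replication were much lower, though the call of the cell cycle list was lost with an estimated correlation (adjusted p = 0.387). MCM3 (comp136441_c1), a subunit of the replicative helicase, fell from 12.2 ± 4.07 CPM (SD, n = 3) to 0.806 ± 0.771 CPM (n = 4), 15.9-fold lower, and MCM4 (comp130132_c0) was 10.5-fold lower, while MCM2 (comp137427_c0), of the same helicase, did not pass (0.18 ± 0.11 on the log2 scale, adjusted p = 0.235). RCA (comp104693_c1) dropped back from 113.0 ± 12.5 to 22.5 ± 4.57 CPM, 4.86-fold lower. PAL1 (comp110051_c0), the entry enzyme of phenylpropanoid synthesis, was 4.76-fold lower, falling from 53.8 ± 20.9 to 12.5 ± 1.31 CPM. DAM2 (comp101885_c0) rose a further 6.05-fold, from 28.1 ± 10.3 to 152.7 ± 9.91 CPM, while SVP (comp110466_c0) did not pass, at 162.8 ± 13.0 and 156.6 ± 6.95 CPM. The clock gene GIGANTEA (GI, comp133368_c1) rose 2.44-fold, from 240.8 ± 18.8 to 580.9 ± 49.8 CPM.

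Here 2943 of the 18885 components rose and 3488 fell in edgeR, 502 and 1415 of them at least 2-fold, so that the large changes were mostly falls. With endodormant replicates 3 and 4 counted as 1 sample, the groups did not overlap in 34.0% of the components, against 5.7% by chance. With endodormant replicates 3 and 4 summed, 5593 components changed, among them 84.9% of the 6431. Without both replicates 3913 changed, and without endodormant replicates 1 and 2, 7276, so the count depended on which pair was left out. Of the tested components, 3194 reach a posterior probability of 0.95 in the authors' deposited table, and 3169 of these are among the 6431. Of 27 lists, 7 moved down and 1 up with the preset correlation, and 0 passed in camera with an estimated correlation (3 at an unadjusted p under 0.05, lowest adjusted p = 0.27), so each list call here rests on the preset value.

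Growth-related lists fell. Of 39 cell cycle components, 23 fell and 4 rose (24 and 6 adjusted over the list alone, median -1.10, adjusted p = 7.11e-05, adjusted p = 0.387 with an estimated correlation). In this list CDC20.1 (comp135019_c0), an activator of the anaphase-promoting complex, rose 2.70-fold, from 471.8 ± 35.0 to 1255.8 ± 81.5 CPM. Its mean centred log2 CPM was higher in endodormant replicates 3 (0.69) and 4 (0.72) than in 1 (0.37) and 2 (0.07), and from -0.63 to -0.41 in ecodormant libraries. Of 19 expansins and xyloglucan endotransglucosylases, which loosen cell walls, 11 fell and 0 rose (12 and 0 adjusted over the list alone, median -1.26, adjusted p = 7.11e-05, adjusted p = 0.27 with an estimated correlation). Expansin-A4 (comp131166_c0) fell from 41.4 ± 17.3 to 11.7 ± 2.56 CPM, and 2 xyloglucan enzymes, comp127998_c0 (AT5G65730) and comp108264_c1 (AT2G36870), were 3.24-fold and 4.59-fold lower. The list's score was 0.14, 0.18, 0.54 and 0.62 in endodormant replicates 1 to 4.

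Of 30 photosynthesis components, 25 fell and 1 rose (26 and 1 adjusted over the list alone, median -1.11, adjusted p = 6.75e-12, adjusted p = 0.309 with an estimated correlation). GAPB (comp122056_c0), of the Calvin cycle, was 7.90-fold lower and the photosystem I subunit PSAF (comp107107_c0) 2.21-fold lower. Of 31 phenylpropanoid components, 18 fell and 2 rose (20 and 2 adjusted over the list alone, median -0.87, adjusted p = 3.92e-07, adjusted p = 0.309 with an estimated correlation). The lignin-pathway genes 4CL2 (comp118680_c0) and CCOAOMT1 (comp107631_c0) were 5.12-fold and 2.07-fold lower. Of 25 shikimate pathway components, which supply the aromatic precursors, 14 fell and 0 rose, also when adjusted over the list alone (median -0.51, adjusted p = 9.87e-05, adjusted p = 0.314 with an estimated correlation). Its members ADT1 (comp123130_c0), CM1 (comp120277_c0) and TRP1 (comp109344_c0) were 2.55-fold, 1.78-fold and 1.61-fold lower. EPSPS (comp123652_c0) fell by 0.29 ± 0.09 on the log2 scale, from 97.3 ± 9.15 to 81.4 ± 4.17 CPM (adjusted p = 0.0152), but not without endodormant replicate 3 (0.0631) or replicates 3 and 4 (0.178), with 0.00442 the lowest of its alternatives. Shikimate and phenylpropanoid scores were also higher in endodormant replicates 3 and 4 (0.30 and 0.27, 0.78 and 0.71) than in 1 and 2 (0.04 and -0.12, 0.18 and 0.04).

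Of 24 clock and light components, 11 rose and 1 fell, also when adjusted over the list alone (median 0.42, adjusted p = 7.62e-04, adjusted p = 0.27 with an estimated correlation). The size moved with the endodormant split: without replicates 3 and 4 the median was 0.19 (adjusted p = 0.00183). RVE8 (comp115633_c0) rose 2.65-fold to 238.6 ± 17.6 CPM and the blue-light receptor CRY1 (comp136844_c0) 1.52-fold. Of 19 jasmonate components, 14 fell and 3 rose (15 and 3 adjusted over the list alone, median -0.97, adjusted p = 0.0403, adjusted p = 0.387 with an estimated correlation). This call was lost without ecodormant replicate 3 (0.0756), without ecodormant replicate 4 (0.0604), without endodormant replicates 3 and 4 (0.0752) and with 1 component per locus (0.0734). The list's medians there were -0.90, -0.91, -0.46 and -0.81. In it JAR1 (comp130019_c0), which makes the active jasmonate conjugate, was 1.76-fold lower, while the receptor COI1 (comp132848_c0) and the jasmonate-degrading CYP94B3 (comp132753_c1) rose 1.39-fold and 3.14-fold. Its scores were 0.19, 0.12, 0.62 and 0.51 in endodormant replicates 1 to 4.

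Of 25 glutathione S-transferases, 9 fell and 0 rose, also when adjusted over the list alone (median -0.28, adjusted p = 0.0448, adjusted p = 0.437 with an estimated correlation). The call was lost without endodormant replicate 1 (0.142), endodormant replicate 2 (0.0887), ecodormant replicate 3 (0.094) or ecodormant replicate 4 (0.0604), without endodormant replicates 1 and 2 together (0.508) and with 1 component per locus (0.072). Members comp128119_c0, the omega-class comp113854_c1 and comp119181_c0 were 1.64-fold, 1.44-fold and 1.24-fold lower.

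Hormone and carbon lists otherwise did not pass. These were gibberellin (1 of 29 rose, 11 fell, adjusted p = 0.0686), abscisic acid (9 of 48 rose, 10 fell, 0.549), auxin (6 of 27 rose, 6 fell, 0.915), cytokinin (1 of 21 rose, 2 fell, 0.915), ethylene (3 of 17 rose, 3 fell, 0.977), strigolactone and branching (2 of 10 rose, 3 fell, 0.977), salicylate and defence (3 of 12 rose, 1 fell, 0.434) and starch and sucrose (8 of 38 rose, 18 fell, 0.12). Adjusted over the list alone, abscisic acid had 9 and 11, auxin 7 and 7, cytokinin 1 and 1 and starch 9 and 20, and the others were the same. The gibberellin list passed without paradormant replicate 1 (0.0223), 2 (0.0302), 3 (0.0293) or 4 (0.0349). Paradormant libraries are not part of this comparison, and the list's median was -0.58 in each of those fits (-0.44 with all libraries). More components passed the filter there (19403 to 19420 tested in place of 18885), so these passes need not rest on single libraries. The gibberellin list also passed without ecodormant replicate 1 (0.0155), 2 (0.0417), 3 (0.0487) or 4 (0.0426). The starch list passed without endodormant replicate 1 (0.0265) or without replicates 1 and 2 (0.0018). GASA14 (comp116270_c0) fell by 3.08 ± 0.55 and GA3 (comp121172_c0) by 1.46 ± 0.29 on the log2 scale. Without ecodormant replicate 3, GASA14 had 2 counts in ecodormant libraries, a ratio of 13.9 with a counting interval from under 4 to 119.1. ABI1 (comp120854_c0) and HAB1 (comp130457_c0), phosphatases that dampen abscisic acid signalling, rose 3.44-fold and 1.46-fold. The auxin importer AUX1 (comp100052_c0) was 2.09-fold lower and AXR1 (comp119015_c0) rose 1.42-fold. The cytokinin-producing IPT5 (comp136680_c0) rose 1.57-fold, LOG5 (comp112631_c1) was 3.25-fold lower, EBF1 (comp136486_c0) and ERF1 (comp92392_c0) were 1.61-fold and 2.84-fold lower, and the strigolactone receptor D14 (comp124889_c1) was 1.80-fold lower (log2 change -0.52 without endodormant replicates 1 and 2). DRM1 (comp136283_c0) rose 1.49-fold to 3586.2 ± 233.2 CPM. WRKY40 (comp129365_c0) and EDS1 (comp119170_c0) rose 1.61-fold and 1.24-fold. SEX4 (comp102735_c0) rose by a further 1.14 ± 0.12 on the log2 scale and the trehalose-phosphate synthase TPS1 (comp132541_c0) rose 2.75-fold. Without endodormant replicates 3 and 4 the calls of LOG5 (0.21), WRKY40 (0.0598) and EDS1 (0.191) were lost.

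The other lists did not pass either. They were flowering-time regulators (1 of 24 rose, 9 fell, adjusted p = 0.28), cold acclimation (6 of 24 rose, 3 fell, 0.451), senescence (3 of 9 rose, 4 fell, 0.977), oxidative stress (2 of 18 rose, 3 fell, 0.962), phloem (3 of 7 rose, 1 fell, 0.549), shoot meristem (3 of 11 rose, 3 fell, 0.977), ribosomal proteins (15 of 176 rose, 38 fell, 0.277), heat shock proteins (13 of 74 rose, 8 fell, 0.448), LEA proteins (0 of 8 rose, 1 fell, 0.915), UDP-glycosyltransferases (6 of 56 rose, 12 fell, 0.956) and ABC transporters (22 of 103 rose, 12 fell, 0.675). Adjusted over the list alone, flowering had 2 and 9 and cold acclimation 7 and 6, and the others were the same. The LEA list was given as words in the annotation, so LEA genes described otherwise are not in it. In the laticifer (4 tested) and secondary wall (1 tested) lists 0 components changed. Median and mean differed in sign for cold acclimation (0.04, -0.05), abscisic acid (0.09, -0.04), phloem (0.30, -0.11) and ABC transporters (0.02, -0.08), all with camera up, and for strigolactone (0.09, -0.15), ethylene (0.12, -0.09) and UDP-glycosyltransferases (0.01, -0.19), all with camera down. Shoot meristem genes had a median of -0.08 with camera up.

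Members that changed include the floral integrator SOC1 (comp117371_c1), 4.52-fold lower, and the cold-response regulator ZAT10 (comp107634_c0), which rose 4.17-fold to 78.4 ± 13.2 CPM. LOS2 (comp115385_c0) rose 1.53-fold, SAG29 (comp134765_c0) 2.43-fold, SUC2 (comp130060_c1) 1.59-fold and UFO (comp110309_c0) 2.13-fold. The chlorophyll-breakdown gene SGR1 (comp136977_c0), the ascorbate peroxidase APX1 (comp124274_c0) and GR1 (comp128105_c1) were 1.67-fold, 1.55-fold and 1.25-fold lower. SEOR1 (comp134729_c0) and the meristem receptor CLV1 (comp134523_c0) were 4.57-fold and 2.24-fold lower. Ribosomal proteins L34 (comp128076_c0) and L7a (comp110594_c0) rose 3.38-fold and 1.79-fold, and chaperone genes comp100078_c0 (AT1G56090) and comp129972_c0 (AT5G02500) 2.48-fold and 1.35-fold. A Lea14 protein (comp126572_c0) was 1.31-fold lower, a call lost without endodormant replicates 3 and 4 (0.0879, with 2.35e-04 the lowest of its alternatives). UGT74E2 (comp116697_c3) rose 3.84-fold and comp127410_c1 (AT5G54010) was 2.25-fold lower. Among ABC transporters comp120123_c0 (AT5G13580) was 13.8-fold lower, and comp132787_c0 (AT5G19410) had 2 counts in ecodormant libraries, a ratio of 50.2 with a counting interval of 13.5 to 419.7.

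The largest rises were those of a ribonuclease-like protein (comp111431_c0, 3.56 ± 0.42 on the log2 scale, 2.77 to 5.45 over its alternatives), comp109495_c0 (AT5G06760, 2.92 ± 0.61, lost without endodormant replicates 3 and 4 at 0.0854, with 3.67e-05 the lowest of its alternatives), comp110221_c0 (AT5G62360, 2.91 ± 0.37, 2.21 to 4.33 over its alternatives), comp137924_c1 (AT1G78020, 2.82 ± 0.21) and comp119762_c0 (AT1G78610, 2.71 ± 0.17). The largest falls included peroxidase 72 (comp114521_c0, 49.0-fold lower, from 17.6 ± 7.01 to 0.366 ± 0.145 CPM), comp105150_c1 (AT2G23540, 42.0-fold), comp102603_c0 (AT4G20390, 40.8-fold) and a lipid-binding protein (comp97211_c0, AT3G22600, 40.3-fold). Without ecodormant replicate 2 the latter had 2 counts in the group, a ratio of 113.7 with a counting interval of 31.2 to 943.0. The component comp133982_c0 (AT5G09530) had 3 counts in ecodormant libraries against 14.7 ± 2.80 CPM in endodormant buds, a ratio of 70.1 with a counting interval of 23.7 to 342.8. Changes in this step moved with the endodormant split too. Without endodormant replicates 1 and 2 the log2 change was 3.23 for DAM2, 2.41 for CYP94B3 (1.65 with all libraries) and 2.64 for UGT74E2 (1.94), and without replicates 3 and 4 it was -1.55 for SEOR1 (-2.19).

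**Figure D3:**
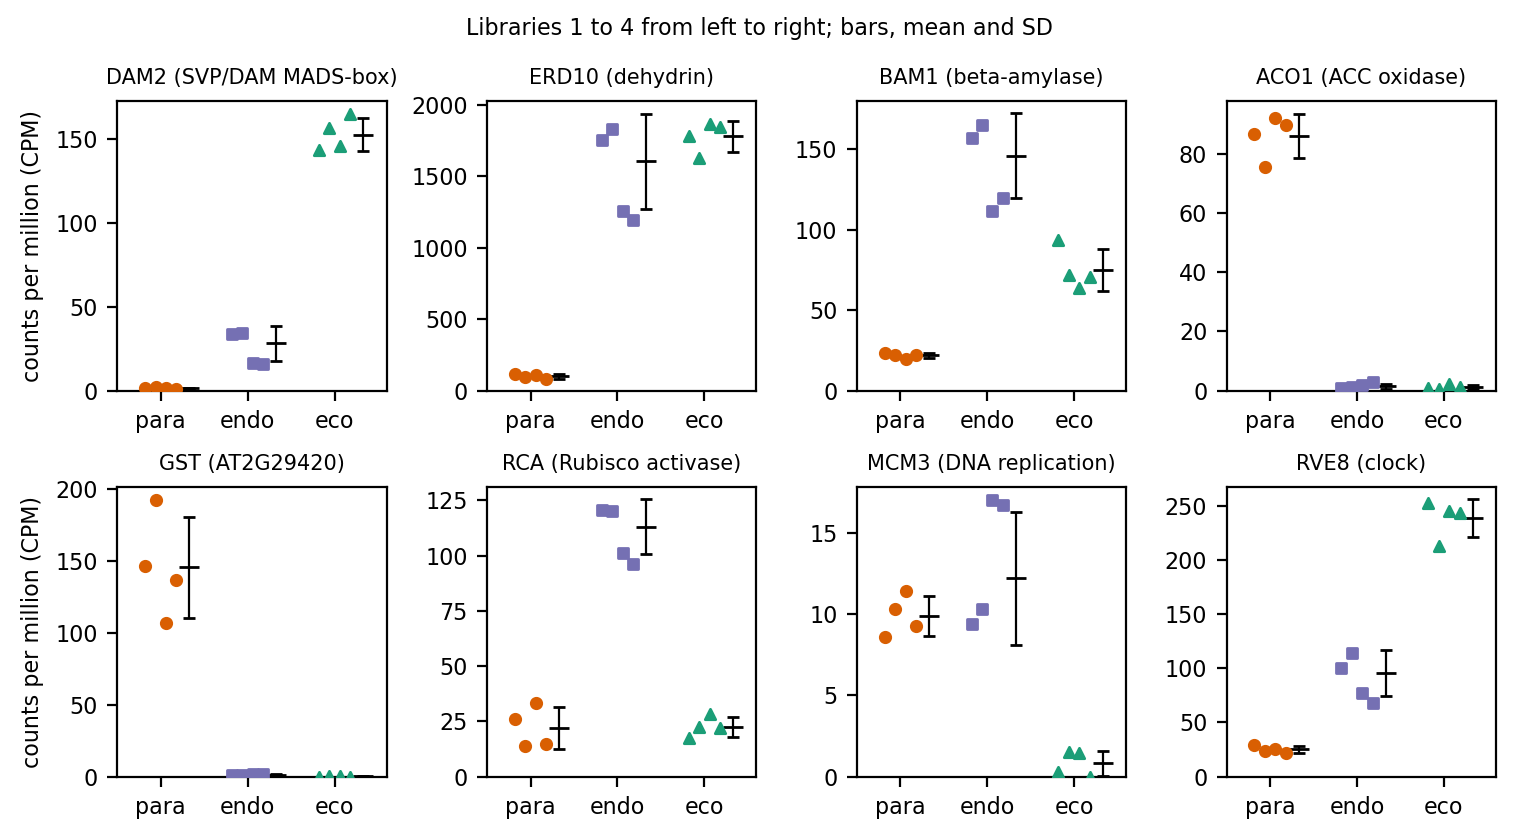
Level (CPM) of 8 genes in each library of paradormant (para), endodormant (endo) and ecodormant (eco) buds, replicates 1 to 4 from left to right, with mean and SD beside them (n = 4, 3 and 4, endodormant replicates 3 and 4 counted as 1 sample). DAM2 and RVE8 were highest in ecodormant buds, BAM1 and RCA in endodormant buds, and ACO1 and the glutathione S-transferase in paradormant buds.

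Ecodormant against paradormant buds gives the net difference between the start and the end of the series. The beta-amylase BAM3 (comp135393_c0) rose 183.5-fold, from 2.39 ± 0.703 to 443.9 ± 51.9 CPM (SD, n = 4 each), and stood at 87.4 ± 44.1 CPM in endodormant buds (n = 3; 112.4 and 113.2 CPM in replicates 1 and 2, 36.0 and 37.0 CPM in 3 and 4). DAM2 (comp101885_c0) rose 105.1-fold, from 1.42 ± 0.294 to 152.7 ± 9.91 CPM, and SVP (comp110466_c0) 1.70-fold. The LEA protein comp102477_c0 rose 180.7-fold to 204.0 ± 58.2 CPM, and the group 3 LEA protein comp75470_c0 had a ratio of 192.2 (counting interval 65.4 to 935.3). The glutathione S-transferase comp105439_c0 had 3 counts in ecodormant libraries, a ratio of 663.9 (226.9 to 3221.7), and comp98228_c0 and comp98726_c0 had 0 counts there, at least 102-fold and 95-fold lower. DRM1 (comp136283_c0) rose 1.59-fold, and EPSPS (comp123652_c0) fell by 0.36 ± 0.08 on the log2 scale (adjusted p = 0.00153), from 104.7 ± 6.31 to 81.4 ± 4.17 CPM.

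In edgeR 5216 components rose and 5660 fell, 2094 and 2480 of them at least 2-fold, and in 52.6% of components the groups did not overlap (2.9% by chance). With endodormant replicates 3 and 4 summed, 11202 changed, among them 99.0% of the 10876. The authors' deposited table has 6883 tested components at a posterior probability of at least 0.95, of which 6825 are among the 10876. Of 27 lists, 3 moved up and 7 down, and the calls of 4 (glutathione S-transferases, ethylene, clock, gibberellin) held with an estimated correlation, at adjusted p = 0.0429 each.

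Glutathione S-transferases were lower (17 of 25 fell, 4 rose, median -2.02, adjusted p = 3.19e-08), as were ethylene genes (14 of 17 fell, 1 rose, median -0.79, adjusted p = 4.20e-08) and gibberellin genes (18 of 29 fell, 4 rose, median -1.22, adjusted p = 0.00238), while clock and light genes were higher (15 of 24 rose, 2 fell, median 1.02, adjusted p = 3.13e-07). Shikimate genes fell (20 of 25, 1 rose, median -0.70, adjusted p = 3.11e-04, adjusted p = 0.263 with an estimated correlation), and so did phenylpropanoid genes (21 of 31, 6 rose, median -1.19, adjusted p = 4.62e-04, adjusted p = 0.344 with an estimated correlation), UDP-glycosyltransferases (31 of 56, 13 rose, median -0.61, adjusted p = 0.00667, adjusted p = 0.25 with an estimated correlation) and expansins (12 of 19, 4 rose, median -1.54, adjusted p = 0.0277, adjusted p = 0.296 with an estimated correlation, and 0.0504 without ecodormant replicate 2). Starch and sucrose genes rose (19 of 38, 7 fell, median 0.30, adjusted p = 4.62e-04, adjusted p = 0.223 with an estimated correlation, and a median of 0.46 without paradormant replicate 3), and so did LEA proteins (4 of 8, 0 fell, median 0.38, adjusted p = 0.0124, adjusted p = 0.125 with an estimated correlation). The median of LEA proteins was from 0.59 to 0.67 when any paradormant or endodormant library was left out. More components were tested in those fits (19403 to 19485 in place of 18885), so the members tested can differ. Adjusted over the list alone, gibberellin had 5 rises and 19 falls, shikimate 2 and 20, phenylpropanoids 7 and 21 and UDP-glycosyltransferases 13 and 32, and the other 6 were the same.

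Lists that did not pass were cold acclimation (13 of 24 rose, 8 fell, adjusted p = 0.182), photosynthesis (6 of 30 rose, 13 fell, 0.456), cell cycle (13 of 39 rose, 19 fell, 0.552), abscisic acid (21 of 48 rose, 19 fell, 0.977), auxin (5 of 27 rose, 10 fell, 0.456), cytokinin (3 of 21 rose, 12 fell, 0.123), strigolactone (5 of 10 rose, 2 fell, 0.456), jasmonate (3 of 19 rose, 6 fell, 0.456), salicylate (3 of 12 rose, 2 fell, 0.627), flowering (5 of 24 rose, 9 fell, 0.456), senescence (2 of 9 rose, 4 fell, 0.839), oxidative stress (4 of 18 rose, 8 fell, 0.671), phloem (2 of 7 rose, 0 fell, 0.293), meristem (5 of 11 rose, 3 fell, 0.456), ribosomal proteins (27 of 176 rose, 74 fell, 0.182), heat shock proteins (15 of 74 rose, 24 fell, 0.455) and ABC transporters (29 of 103 rose, 42 fell, 0.299). Adjusted over the list alone, ABC transporters had 30 and 43, and the others were the same. With 1 component per locus cold acclimation passed upward (median 1.37, adjusted p = 2.19e-04) and oxidative stress downward (median -0.74, adjusted p = 0.0214). In the laticifer list 3 of 4 components rose (4 adjusted over the list alone), and the 1 secondary wall component did not change. Signs differed for abscisic acid (median 0.10, mean -0.12, camera down), auxin (0.04, -0.37, down) and senescence (-0.22, -0.23, up).

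Between the endodormant and the ecodormant harvest some changes were undone and others went further. Temperature, bud age and time since the spray differ together in this step. Of the 8445 components that changed in the ramp down, 1662 (19.7%) changed in the opposite direction in the cold and 1638 (19.4%) in the same direction, while 6345 (75.1%) differed from paradormant buds in the same direction at the end. The paradormant libraries that both comparisons use raise this share to an extent not measured here. The balance of opposite and same direction depended on the endodormant libraries, with 2263 and 1216 without replicates 1 and 2, 995 and 1014 without replicates 3 and 4, and 1348 and 1420 with replicates 3 and 4 summed. RCA and JAR1 are examples of genes that rose and fell back, RVE8, SEX4 and DAM2 of genes that rose in both steps, and GASA14, GA3 and EBF1 of genes that fell in both. In all, 1057 components rose and then fell, where independent lists would share 796, and 892 rose in both steps, where independent lists would share 671. A further 605 fell and then rose (645 if independent) and 746 fell in both (764 if independent). As both steps use the endodormant libraries, their log2 changes had a covariance of -0.022 against -0.027 in data simulated without change, and with separate endodormant libraries in each step it was 0.118 (replicates 1 and 2 in the ramp down, 3 and 4 in the cold) and -0.045 (the reverse), so its sign depended on which libraries were used. With 1 library of each pair in each step, chosen after seeing this, it was -0.011 and 0.000.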

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

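Of the tests below, those of swapped labels, of the highest components and the spray for glutathione S-transferases, and all 3 for clock genes were chosen only after the result was seen.

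Endodormant replicates 1 and 2 lay 33.9 units from replicates 3 and 4 on the second principal component. Reads from other organisms are argued against as the whole cause, since 95.6% of the gap remained with plant (Viridiplantae) components alone. As these are 16812 of the 18885 tested components, a smaller part from other reads is not excluded. Depth is argued against by the totals, since replicates 1 and 2 (3541887 and 3582278 counts) lay between replicates 4 and 3 (3356634 and 3613270). Thinning each library to the smallest total left 100.2% of the gap, but it removed too few reads to decide. A swap of labels with the ecodormant group is argued against too: 0 ecodormant libraries were nearer to endodormant replicates 3 and 4 (mean correlation 0.890 to 0.922) than to their own group (0.969 to 0.977). The labels give these libraries no group that would part them, so no biological explanation was tested. On the third component (5.6% of variance), replicates 1 to 4 scored 25.5, 34.3, -12.7 and -14.1 in the endodormant group. In the ecodormant group they scored 21.3, 0.3, -35.7 and -14.7, and in the paradormant group 1.1, 5.4, -9.7 and -0.9. Whether a factor shared by libraries of the same number lies behind this stays open. Residual correlations of same-numbered libraries ran from -0.09 to 0.29, over 0.1 in 4 of 12 pairs. A shared source of RNA for replicates 3 and 4, or 1 library sequenced under a pair of numbers, stays open as the reason these libraries are nearly copies. The chi-square between them lay above counting noise over all components (1.22 per component, p = 3.88e-72) and little above it over components of a single contig (1.13, p = 0.0479), and as reads were also assigned by estimate this does not tell the 2 apart.

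Glutathione S-transferase genes were lower in endodormant than in paradormant buds, with a median log2 change of -1.42. A few genes taking most of the counts is argued against: the 10 highest components held from 4.65% of counts in a paradormant to 5.49% in an endodormant library, which changes all other components by at most -0.01 on the log2 scale. Reads shared between paralogs are argued against too, as the summed level of all 118 components of the family in the lowest paradormant library was 1.43 times that in the highest endodormant library (3904, 4059, 3343 and 3315 CPM in endodormant and 6060, 7378, 5812 and 6492 CPM in paradormant replicates 1 to 4). The spray 7 days before the paradormant harvest could account for high levels there, and so could day length, temperature or the state of the bud; with 0 libraries from unsprayed plants these cannot be told apart.

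Clock and light genes were higher after the ramp down, a list call lost with an estimated correlation (adjusted p = 0.0838), and again after the cold. In the second step the list passed (adjusted p = 7.62e-04, 11 of 24 up and 1 down) with both groups at 8 h of light at harvest, a call lost with an estimated correlation (adjusted p = 0.27). As ecodormant plants had 8 more weeks at 8 h, a longer stay under short days and the cold cannot be told apart. The endodormant libraries that stand apart are argued against as the whole cause, since the list passed with either pair left out (higher adjusted p = 0.00183), although its median was 0.19 without replicates 3 and 4 and 0.42 with all libraries. For the first step, a shift of clock phase at the fixed harvest hour of about 10 am may play a part: 2 of 3 evening-phased components rose (GI and TOC1), as did 2 of 2 morning-phased ones (LHY and RVE8), too few to decide, so a shift of phase and a change of level cannot be told apart. For the second step lower temperature, the 8 further weeks of cold and short days, the age of the bud and time since the spray stay open as untested.

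Other groupings of the libraries were tried to see whether the counts of changed components exceeded chance. In each comparison only the real grouping, 1 of 35 splits, gave as many. Fitted on those groups alone, edgeR called 7990 components in endodormant against paradormant and 5553 in ecodormant against endodormant buds. In ecodormant against paradormant buds it called 10651, and the highest other split of each comparison called 0. Every other split mixes libraries of both states, which widens the spread within its groups, so 0 calls there cannot exclude chance. Endodormant replicates 3 and 4, nearly copies, count as separate libraries in these splits. At an unadjusted p under 0.05 the real splits gave 9245, 7473 and 11356 components, and the highest others 1656, 3481 and 1554.

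Among 334 groups of 4 libraries, 21 (6.3%) held a library far from the other 3, where chance gives about 1 in 20, so most of these may be chance. In the next sentences the range of the other libraries stands in brackets. Paradormant replicate 3 had 0.082% of counts on fungal (0.056 to 0.059) and 0.007% on bacterial components (0.003 to 0.004). Ecodormant replicate 2 had a starch and sucrose score of -0.06 (0.17 to 0.20), and paradormant replicate 2 an LEA score of -1.49 (-1.05 to -0.98). The other 17 were log2 CPM values of named genes. In paradormant replicate 2 these were comp98726_c0 at 4.83 (at most 4.30), the glutathione S-transferase comp119181_c0 at 9.82 (9.64 to 9.67) and peroxidase 72 (comp114521_c0) at 2.0 (1.05 to 1.18), and in paradormant replicate 4 PP2CA (comp122597_c1) at 0.07 (0.39 to 0.45) and CYCD1;1 (comp131195_c0) at 5.07 (5.40 to 5.46). In ecodormant replicate 1 they were the glucuronosyltransferase comp82823_c0 at -0.24 (-0.84 in the others), OMT1 (comp111762_c1) at 5.20 (4.00 to 4.13), comp133982_c0 at -0.84 (-0.25 to -0.22) and the omega glutathione S-transferase comp113854_c1 at 9.01 (8.70 to 8.75), and in ecodormant replicate 2 the glycosyltransferase comp88488_c0 at -0.22 (1.38 to 1.51). In ecodormant replicate 3 they were ARR9 (comp74955_c0) at 2.0 (2.47 to 2.54), the ABC transporters comp109384_c0 at 3.24 (4.05 to 4.18) and comp120123_c0 at -0.84 (1.38 to 1.56), HAB1 (comp130457_c0) at 7.72 (7.87 to 7.89) and GR1 (comp128105_c1) at 7.78 (7.63 to 7.65). In ecodormant replicate 4 they were WRKY40 (comp116411_c1) at 4.27 (4.90 to 4.98) and peroxidase 72 at 0.19 (-0.25 to -0.22). On this scale -0.84 is a library with 0 counts, so values near it differ by few counts. The component comp133982_c0, for example, had 3 counts in all ecodormant libraries together.

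Counts on components whose best protein match is from another kingdom, a share that no comparison tests, lay above the level that 3 counts give (8.94e-05%). They were highest in endodormant replicate 1, at 0.174% for animals (0.039% to 0.140% in the other libraries), 0.132% for fungi (0.050% to 0.097%) and 0.015% for bacteria (0.002% to 0.010%).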

How the results depend on the processing

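Summing endodormant replicates 3 and 4 and leaving out either endodormant pair were chosen after seeing the data, and the other alternatives before. No list or named gene call reversed. The counts of 8445, 6431 and 10876 changed components stayed within 1.5 times under DESeq2 size factors, DESeq2, voom, both filters, a fit of the 2 groups alone and a block for replicate number (8770, 6820 and 11157, with 11, 8 and 10 lists). By construction fewer passed with a 2-fold limit (3081, 1917 and 4574). With contigs in place of components 5122 passed in endodormant against paradormant and 2627 in ecodormant against endodormant buds; the cause was not tested. Without endodormant replicates 3 and 4, 3913 components changed in ecodormant against endodormant buds. Without replicates 1 and 2, an equal loss of libraries, 7276 changed. Without endodormant replicates 3 and 4, 995 of the ramp-down changes went the opposite and 1014 the same way in the next step (1662 and 1638 with all libraries). Without endodormant replicates 1 and 2 these were 2263 and 1216. The order of these counts turned in several settings, among them without ecodormant replicate 1 (1475 and 1511). With an estimated correlation 4, 0 and 4 lists passed in place of 9, 8 and 10. With the 1000 most variable components the first principal component held 73.1% in place of 59.0%. Leaving out 1 library at a time gave 7590 to 8825, 5215 to 6729 and 10221 to 11318 changed components, 8 to 11, 7 to 9 and 9 to 10 lists, 1269 to 1844 opposite, 1302 to 1662 same-way and 5837 to 6622 net changes, and 56.1% to 63.6% on the first component. The edgeR fits without 1 library also tested more components (19403 to 19485 in place of 18885), so a change there need not come from the library left out. Of 156 named calls 7 were lost in any of 19 alternatives, and of 27 list calls 19 were, 4 of them on leaving out 1 library. Voom, the filters and contigs were not among these 19. Most named genes were chosen for groups that do not overlap and large changes or small adjusted p, so their stability does not carry over to other calls. Of the 6431 calls in ecodormant against endodormant buds, 3532 remained without endodormant replicates 3 and 4. Whether replicate numbers pair the libraries stays open: 4 of 12 same-numbered pairs had a residual correlation over 0.1 (-0.09 to 0.29). In 5 of 12 the best match was the library of the same number. For replicate 3 the correlation was 0.23 (endodormant with paradormant), 0.29 (ecodormant with endodormant) and 0.17 (ecodormant with paradormant). In simulated data few changes of 1.5-fold were recovered (28.8% in endodormant against paradormant and 22.7% in ecodormant against endodormant buds). Far fewer components were changed there than passed here, which makes the adjusted threshold stricter, so this recovery does not measure a limit of depth. Recovery of 1.5-fold changes at the real share of changed components was not tested.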

Other observations

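The list of suberin genes and both tests of it were chosen only after the fall of some of its members had been seen.

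Genes that make suberin, the waxy polymer of protective cork layers, were mostly lower in ecodormant than in endodormant buds. Over the 12 tested members, 9 rose and 1 fell in endodormant against paradormant buds (median log2 change 2.78), and 0 rose and 11 fell in ecodormant against endodormant buds (median -3.61). The fatty acid hydroxylase CYP86A1 (comp123706_c0) went from a mean of 4.30 CPM to 39.0 and then 1.31 CPM (4 libraries each), with changes of 3.17 ± 0.20 and -4.85 ± 0.25 on the log2 scale. CYP86B1 (comp123544_c0) changed by 3.31 ± 0.38 and -5.16 ± 0.49, the acyltransferase GPAT5 (comp118768_c0) by 3.05 ± 0.29 and -4.31 ± 0.35, and the feruloyl transferase ASFT (comp107859_c1) by 2.95 ± 0.26 and -3.48 ± 0.28. The transporters ABCG6 (comp120123_c0) and ABCG20 (comp109384_c0) and the lipase-like GELP96 (comp105150_c1), named above for their large changes, are members too. A further ASFT component (comp130615_c1) went the other way in the ramp down, by -1.89 ± 0.36, and did not pass in the cold (adjusted p = 0.177).

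A hypothesis of this re-examination is that suberin synthesis genes are regulated together across the cold. Values of 4 members (CYP86A1, ABCG6, ABCG20, GELP96) had been seen when the list was written, so the test used the other 8: 0 rose and 7 fell in ecodormant against endodormant buds (median -2.77, adjusted p = 2.53e-11, adjusted p = 0.00239 with an estimated correlation), a result consistent with the hypothesis. The same 8 had 5 rises and 1 fall in the ramp down (median 1.84, adjusted p = 4.81e-04), a call lost with an estimated correlation (adjusted p = 0.0557). These p-values were adjusted only over the list of these 8 and that of all 12 members. The 8 are components, and ASFT and FAR4 each match more than 1 of them. The endodormant libraries that stand apart are argued against as the cause of the fall, since the same 8 fell as a list with either pair left out (higher adjusted p = 9.73e-12). Transcript levels alone do not show whether suberin was laid down, and the spray, the cold and the age of the bud stay open as causes.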
